A study of Mus musculus with 8 samples.

How the data were processed

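The libraries came from N2a cells, a mouse neuroblastoma line, collected 48 h after transfection with a small interfering RNA against Emg1 or with a control one. Per the labels' protocols, poly(A) RNA was fragmented and incubated with an antibody against N6-methyladenosine (m6A), and stranded libraries were made from the precipitated RNA and from input RNA. The 8 libraries formed 4 groups of 2: m6A immunoprecipitation (IP) and input, each after Emg1 knockdown and after control. Nothing in the labels says whether the libraries of a group came from separate cultures, so the spread between them may be technical. The authors' p-values for input RNA measure that spread, and whether those for peaks do is not known. The tests of lists and of peak shares below take genes or peaks as units, so their p-values do not measure spread between libraries.

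Per the submitters' processing notes, Trimmomatic, HISAT2 and DESeq2 were used with the mm10 build. The read counter, the annotation, the peak caller and the tool versions are not given in the sources used here. One table held the authors' own DESeq2 results for 16279 genes. Its mean expression column is a signal, the mean normalized count over the libraries of the fit, per the file headers. The log2 fold change and its standard error (SE) are log2 values deposited by the authors, and the Wald statistic is a score that equalled the fold change divided by its SE. The p-value and the adjusted p-value were deposited by the authors. An adjusted p was given for 12807 genes, and the 3472 genes without one all had a mean at or below 22.7. The file names no direction. Emg1 had a negative value, and the fold changes are read as knockdown over control.

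The other table was a list of 2114 differential m6A peaks. The fold enrichment of IP over input is a ratio deposited by the authors for each peak, and the change between conditions is a log2 value deposited with log10 values of a p-value and a false discovery rate. The largest false discovery rate in the list was 0.0282. The file does not say which condition is the numerator of the change, so peaks are called positive-change or negative-change with the sign as deposited. Whether replicates were pooled for the peak test is not given in the sources used here. A score column of the list, deposited by the authors, held the p-value of the peak and was not used here. Only differential peaks were analysed here, so no share of all peaks can be given.

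Neither table holds values per library. The depth of each library is therefore unknown, and no count model was refitted. The precision of the fold changes is that of the SE in the authors' deposited table, with a median SE of 0.10 at means of at least 100 and 1.04 below. The design fixed before the data were examined provided for this case: genes were called by the authors' adjusted p under 0.05. Annotated transcript position and the DRACH motif were planned and were not analysed here, since no exon annotation or genome sequence was used.

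The 30 gene lists were fixed before the data were examined, and 8 members were matched through older symbols of a RefSeq gene table of the same build. Lists with at least 5 measured members were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the Wald statistics, with a preset inter-gene correlation of 0.01. The p-values were adjusted by the Benjamini-Hochberg method over the 28 lists tested. The median log2 fold change of each list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. An inter-gene correlation could not be estimated without values per library, and a preset of 0.05 was the alternative. Other alternatives were rank statistics, log2 fold changes as statistics, a minimum mean of 100, other thresholds, adjustment over all genes, and centring on the median of genes with a mean of at least 100, which was 0.01.

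The split of peaks by sign was compared with equal shares by an exact two-sided binomial test that treats peaks as independent, which they are not. Intervals of shares are 95% exact Clopper-Pearson intervals. Genes with peaks of one sign were compared with input calls by two-sided Fisher exact tests. Lists were tested for peaks the same way, over genes with a mean of at least 2.19, the lowest among genes with a peak. Position was the peak midpoint as a percent of the RefSeq gene span, introns included, for the 2026 peaks with the midpoint inside the span of a gene of that name. This measure was chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

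Named input genes were Emg1, the 10 rising and 10 falling genes with the largest change at an adjusted p under 0.05 and a mean of at least 100, and up to 4 members per list with the smallest adjusted p, or up to 2 where none passed. Unnamed predicted genes were left out of the 10. Named peaks were the 10 highest and 10 lowest changes with 1 per gene, peaks on Emg1 or m6A machinery genes, up to 10 genes with both a peak and an input change, and up to 4 list members with the smallest peak p. The rule was fixed before the data were examined, and some genes it names are not reported here.

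The calculations were tested on simulated data. With 200 of the genes changed, thresholding of adjusted p over 12807 genes recovered 66.0% of genes changed by 0.5 and 84.0% of genes changed by 1 on the log2 scale, and 3.23% of calls were unchanged genes. Each fold change was drawn with the deposited SE of its gene and tested against that same SE. The accuracy of SEs from 2 libraries per group was therefore not tested. Fewer genes were changed than the 4174 called in the data. The list test called the 1 moved list and 0 of 27 others, in a single draw with genes simulated as independent. False list calls that come from correlated genes were therefore not tested.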

Results

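RNA abundance and m6A were measured in N2a cells, a mouse neuroblastoma line, after knockdown of Emg1, which encodes a methyltransferase of 18S ribosomal RNA. Input RNA and m6A-immunoprecipitated RNA were sequenced, with 2 libraries for each of the 4 groups. The comparisons asked which transcripts and which m6A peaks differed between knockdown and control cells, in a study on the influence of EMG1 on m6A in mRNA. The tables give no value per library, so the spread between replicates is known only through the SE and adjusted p of the authors' tests.

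Emg1 itself fell by 1.73 ± 0.11 (log2, SE) in input RNA in the authors' deposited table, to 30.2% of control, with an adjusted p of 3.37e-54. By the authors' adjusted p, 4174 of 12807 genes changed, of which 2187 rose and 1987 fell. Most changes were small: the median absolute log2 fold change of the changed genes was 0.38. At least 2-fold changes were seen for 234 of these genes, 49 higher and 185 lower, so the split by direction depended on the size of change counted.

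The genes ranked here had a mean of at least 100 and an adjusted p under 0.05, without unnamed predicted genes. Among them the steepest falls included Tppp3, a tubulin-binding protein, at -2.14 ± 0.09, and Adm, the precursor of adrenomedullin, at -2.08 ± 0.32 (log2, SE) in the authors' deposited table. Eif4ebp1, a translation repressor that binds eIF4E, fell by 1.74 ± 0.07 and had an adjusted p of 8.2e-136. Nelfe, a subunit of the negative elongation factor, fell by 1.76 ± 0.13, and Pparg, a nuclear receptor of lipid metabolism, fell by 1.68 ± 0.25 in the authors' deposited table. The remaining names among the 10 lowest were Fam101a, Selenbp2, Ten1, Emg1 and Sparcl1, between -1.92 and -1.71. Among the same ranked genes the largest rise was that of Htr3b, a subunit of the serotonin type 3 receptor, at 2.12 ± 0.24 in the authors' deposited table. Its partner subunit Htr3a rose by 1.26 ± 0.07. Nfic, a transcription factor, rose by 1.39 ± 0.08, and Lcn2, a secreted iron-siderophore binder, by 1.81 ± 0.30 in the authors' deposited table. Cp, Dio2, Hist1h2af, Meg3, Ier5l and Acp1 completed the 10 highest, between 1.21 and 1.60.

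Cholesterol synthesis genes fell together. Of 21 measured members, 20 fell and 0 rose, with a median log2 fold change of -0.63, below all 10000 matched random lists (cameraPR adjusted p = 2.49e-26). Fdps and Msmo1, enzymes of the pathway, fell by 1.11 ± 0.08 and 1.11 ± 0.09, and Hmgcs1, which makes HMG-CoA, by 0.99 ± 0.08 in the authors' deposited table. Adjusted over the list alone, the count was also 20.

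Genes of the integrated stress response also fell, 16 against 1 that rose among 23 with an adjusted p (median -0.35, cameraPR adjusted p = 1.12e-10). They included the asparagine synthetase gene Asns at -0.50 ± 0.05, Trib3 at -0.64 ± 0.08 and Chac1 at -0.82 ± 0.10 in the authors' deposited table. In the endoplasmic reticulum unfolded protein response list, 11 members fell and 2 rose (cameraPR adjusted p = 0.000185), with the chaperone gene Hspa5 at -0.40 ± 0.06 and Xbp1 at -0.47 ± 0.07 in the authors' deposited table. In the glycolysis and hypoxia list, 12 fell and 2 rose (median -0.30, cameraPR adjusted p = 1.88e-09). The authors' deposited table gave Ero1l at -1.33 ± 0.07, the glycolytic enzyme gene Pgam1 at -0.90 ± 0.06 and Bnip3 at -0.88 ± 0.09. Adjusted over the list alone, the falling members of these 3 lists were 16, 12 and 13.

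The ribosome divided into falling structural genes and rising assembly genes. Of 32 small subunit ribosomal protein genes, 18 fell and 3 rose, and of 46 large subunit genes 27 fell and 2 rose, with medians of -0.16 and -0.20 (cameraPR adjusted p = 3.12e-10 for each). Rps19 fell by 1.38 ± 0.07 and Rpl39 by 0.65 ± 0.05 in the authors' deposited table. Ribosomal protein genes have many near-identical pseudogenes, and their counts are uncertain where reads could be split. Hosts of small nucleolar RNAs fell as well, 7 against 1 (cameraPR adjusted p = 0.000244), among them Snhg12 at -0.72 ± 0.11 and Snhg5 at -0.54 ± 0.08 in the authors' deposited table. Adjusted over the list alone, the falling members of these lists were 19, 28 and 8.

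By contrast, 29 of 51 genes of the small subunit processome and 18S maturation rose and 1 fell (median 0.23, cameraPR adjusted p = 7.25e-09). Utp20 rose by 0.61 ± 0.08, Heatr1 by 0.56 ± 0.07 and Wdr46 by 0.58 ± 0.09 in the authors' deposited table. Large subunit assembly factors rose in 19 cases and fell in 2 (cameraPR adjusted p = 9.35e-06), with Mdn1 at 0.57 ± 0.06 and Senp3, which fell, at -0.62 ± 0.08 in the authors' deposited table. Of 12 rRNA modification enzyme genes, 6 rose and 0 fell (cameraPR adjusted p = 0.00248), including the acetyltransferase gene Nat10 at 0.50 ± 0.08 and the methyltransferase gene Nop2 at 0.40 ± 0.07 in the authors' deposited table. The rising members adjusted over the list alone were 30, 22 and 7.

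Several writer and reader genes of m6A rose, and the demethylase genes did not pass. Of 9 writer and cofactor genes, 6 rose and 0 fell (median 0.32, cameraPR adjusted p = 0.0024), and 7 rose when adjusted over the list alone. Zc3h13, a cofactor of the writer complex, rose by 0.52 ± 0.09, the methyltransferase gene Mettl16 by 0.38 ± 0.10 and Rbm15 by 0.30 ± 0.09 in the authors' deposited table. Of the writer core, named after the values were seen, Mettl14 rose by 0.32 ± 0.10 (adjusted p = 0.00537) and Mettl3 did not pass at 0.32 ± 0.13 (adjusted p = 0.0535) in the authors' deposited table. Of 10 reader genes, 6 rose and 1 fell (cameraPR adjusted p = 0.00996), led by Fmr1 at 0.94 ± 0.10 and Ythdf2 at 0.48 ± 0.08 in the authors' deposited table; adjusted over the list alone, 6 rose and 2 fell. With the rank form of the test the readers did not pass (adjusted p = 0.18). The demethylase genes Fto at -0.05 ± 0.07 and Alkbh5 at -0.04 ± 0.06 had adjusted p of 0.633 and 0.645 in the authors' deposited table.

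Cell cycle and progenitor genes rose. In the G1/S list 16 rose and 3 fell (cameraPR adjusted p = 8.32e-07), with Cdt1, a replication licensing factor, at 0.83 ± 0.08 and cyclin D1 (Ccnd1) at 0.57 ± 0.05 in the authors' deposited table. In the G2/M list 15 rose and 2 fell (cameraPR adjusted p = 0.000173), with Foxm1 at 0.49 ± 0.07 and Mki67 at 0.44 ± 0.07 in the authors' deposited table. Of 20 sympathoadrenal and neural progenitor genes with an adjusted p, 14 rose and 0 fell (cameraPR adjusted p = 1.85e-06). The authors' deposited table gave the transcription factor genes Insm1 at 1.18 ± 0.11 and Phox2a at 0.59 ± 0.07. Adjusted over the list alone, 18, 17 and 14 members rose.

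The calls of 3 further lists were less robust. Interferon response genes fell in 8 cases and rose in 0 (cameraPR adjusted p = 0.0297), with Oas1a at -1.34 ± 0.20 and Usp18 at -0.83 ± 0.20 in the authors' deposited table. Translation factors fell in 13 cases and rose in 9 (cameraPR adjusted p = 0.0232), where Eif4e fell by 0.71 ± 0.08 and Eif3g rose by 0.46 ± 0.06 in the authors' deposited table. The falling members of that list include the repressor gene Eif4ebp1 (-1.74 ± 0.07), which had its smallest adjusted p, 8.2e-136. The list was not tested without Eif4ebp1. The median of the translation factors, -0.05, lay at percentile 8.4 of the matched random lists, so it did not stand apart from them. Immediate early genes rose in 5 cases and fell in 1 (cameraPR adjusted p = 0.042), with Myc at 0.54 ± 0.08 and Junb at 1.01 ± 0.26 in the authors' deposited table. With a preset correlation of 0.05 these 3 calls were lost (adjusted p = 0.125, 0.136 and 0.123), and the other 15 calls held. The rank form ended the call of the translation factors (adjusted p = 0.477), and a minimum mean of 100 that of the immediate early genes (adjusted p = 0.0926). With log2 fold changes in place of Wald statistics, 0 of the 28 lists passed. Adjusted over the list alone, 8 interferon genes fell, 15 translation factors fell and 10 rose, and 5 immediate early genes rose and 1 fell.

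The remaining lists did not pass. Nuclear-encoded oxidative phosphorylation genes fell in 10 cases and rose in 3 (cameraPR adjusted p = 0.0581), with Atp5c1 at -0.42 ± 0.06 in the authors' deposited table. Targets of p53 fell in 5 cases and rose in 2 (cameraPR adjusted p = 0.322), and mitochondrial ribosomal protein genes fell in 5 and rose in 2 (adjusted p = 0.449). Neuronal maturation genes went both ways, 7 up and 4 down (cameraPR adjusted p = 0.506), with Stmn2 at -0.65 ± 0.06 and Ncam1 at 0.57 ± 0.06 in the authors' deposited table. Heat shock chaperones rose in 1 case and fell in 3 (cameraPR adjusted p = 0.582). Genes of the replication-dependent histone list rose in 3 cases and fell in 3 (adjusted p = 0.674); their median was 0.31 while the test statistic pointed down, with H1f0, a replication-independent member of that list whose mRNA is polyadenylated, at -0.88 ± 0.05 in the authors' deposited table. The median and the test also differed in sign for heat shock chaperones and fibroblast markers, and the mean differed from one or both for neuronal maturation, macrophage and glial markers. Among markers of other cell types, the fibroblast gene Fn1 rose by 0.63 ± 0.05 and Pdgfrb fell by 0.98 ± 0.19, and the leukocyte gene Cd74 fell by 0.74 ± 0.12 in the authors' deposited table. The lists of fibroblasts, macrophages and leukocytes, endothelium and epithelium, and glia had cameraPR adjusted p of 0.488, 0.488, 0.682 and 0.915. Adjusted over the list alone, oxidative phosphorylation, p53, mitochondrial ribosomal protein and neuronal maturation genes rose in 3, 2, 1 and 7 cases and fell in 10, 5, 5 and 4. None of the 13 mitochondrially encoded transcripts was matched in the table.

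**Figure D1:**
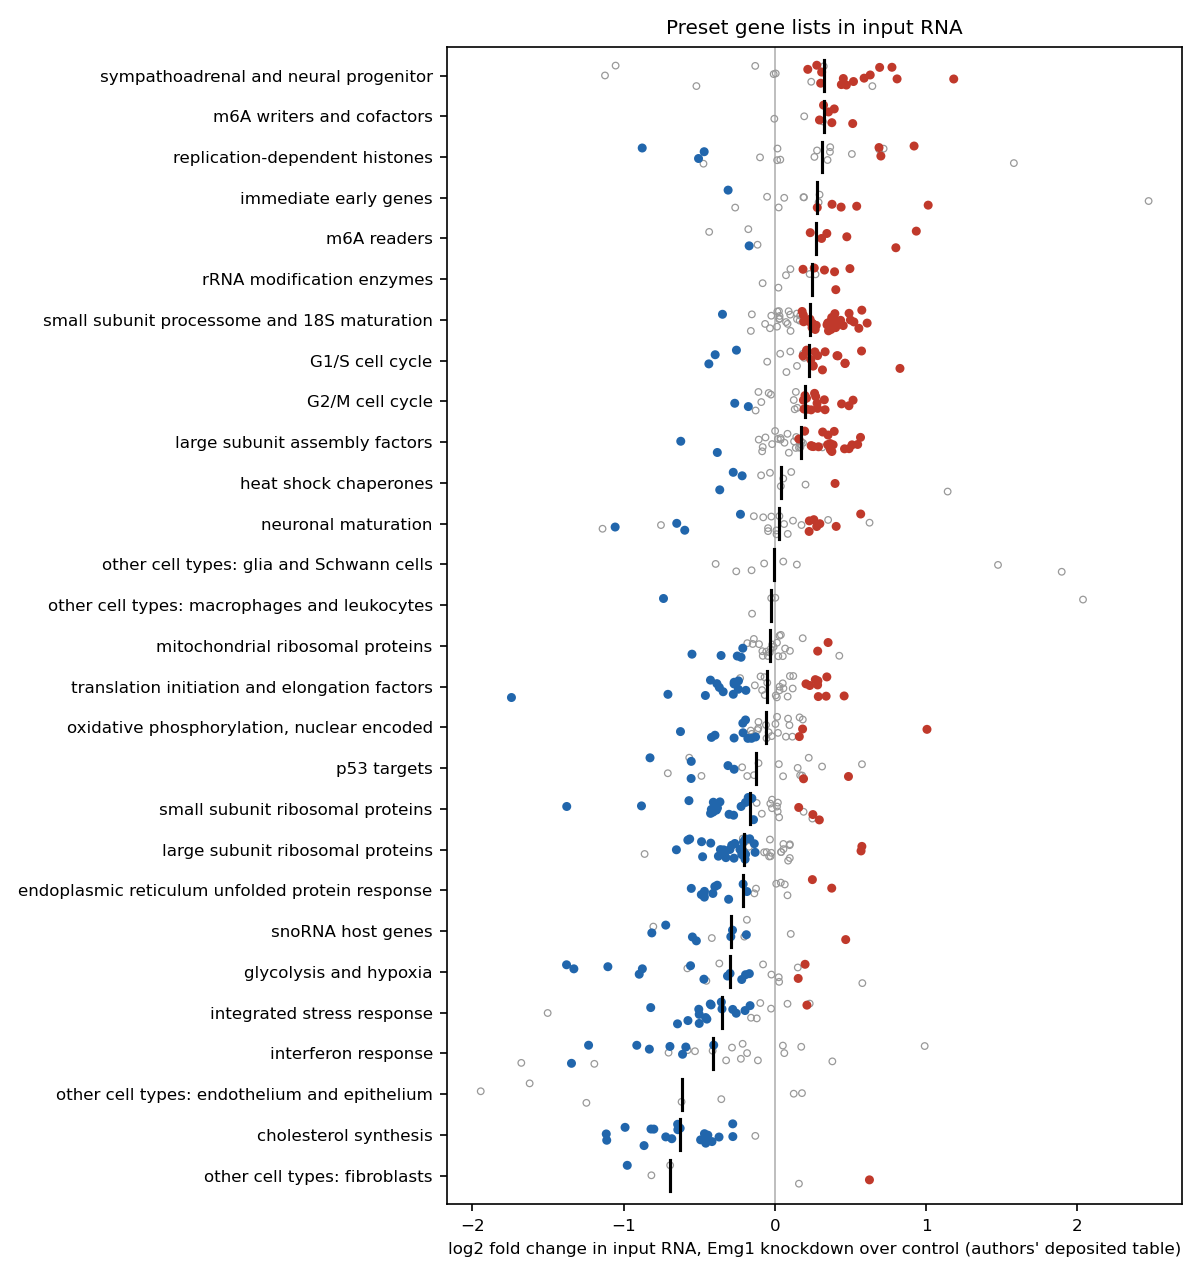
Log2 fold change in input RNA, Emg1 knockdown over control, for each measured member of the 28 lists, from the authors' deposited table. Red and blue points are genes that rose or fell at an adjusted p under 0.05, open points are the others, and black bars are medians; cholesterol synthesis has a median of -0.63 and the small subunit processome one of 0.23.

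Differential m6A peaks were found in both directions. Of the 2114 peaks on 1912 genes, 1123 had a negative and 991 a positive change, a negative share of 53.1% (95% exact interval 51.0 to 55.3, exact binomial p = 0.00437). The file does not state which condition is the numerator, so the sign cannot be read here as gain or loss after knockdown. Peaks of 1 sign were carried by 986 genes for negative and 889 for positive changes, and 37 genes had both. The median change was -0.72 for negative and 0.75 for positive peaks on the log2 scale.

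The most negative changes were on Ctnnb1, which encodes beta-catenin, at -6.26 (mm10 chromosome 9, 120933430 to 120933580), and on Itgb1, which encodes integrin beta-1, at -5.86 (chromosome 8, 128685744 to 128685864), in the authors' deposited table. Ankrd13c, Urgcp, Ppp2ca, Phox2a, Qrich1, Mgat2, Syap1 and Scand1 followed, between -4.75 and -3.63. On the positive side, Edem1, a factor of endoplasmic reticulum protein degradation, had a change of 3.02 (chromosome 6, 108855740 to 108855800) in the authors' deposited table. Rbl1, Mdn1, Hcn3, Sumf1, Rfx5, Pcyt1a, Slc36a1, Gemin4 and Ilvbl followed, between 2.65 and 2.12. Fold enrichments in these 20 peaks lay between 1.32 and 6.05, and the peak table gives no error for a change. The 10 negative-change peaks, except that on Scand1, had midpoints in the first 10% of the gene span. None of the 10 positive-change peaks did.

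No differential peak was on Emg1. Among the m6A machinery, the authors' deposited table held negative-change peaks on the writer cofactor gene Wtap at -1.04 (chromosome 17, 12975271 to 12980827), the demethylase gene Alkbh5 at -0.95 (chromosome 11, 60557883 to 60558003) and the reader gene Hnrnpa2b1 at -0.53 (chromosome 6, 51463446 to 51464526). Their fold enrichments of IP over input were 13.3, 1.36 and 1.35, where the median of all differential peaks was 5.525. The peaks on Alkbh5 and Hnrnpa2b1 were thus only weakly enriched.

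Peaks of the 2 signs differed in place and strength. Of 951 positive-change peaks placed on a gene span, 49.6% lay in the last 10% of the span (95% exact interval 46.4 to 52.9), against 24.2% of 1075 negative-change peaks (21.7 to 26.9; Fisher exact p = 1.05e-32). Among peaks of 1 block, whose midpoint cannot fall in an intron of the peak, the shares were 63.3% and 47.1% (odds ratio 1.93 against 3.09 for all, Fisher exact p = 4.5e-07), and 65.3% of positive-change but 37.6% of negative-change peaks had 1 block. In the first 10% the order was the other way, 2.31% against 12.7% (Fisher exact p = 1.17e-19). The span includes introns, and whether a peak lay in an untranslated region or in coding sequence was not analysed here. Fold enrichment of IP over input, the authors' value per peak, had a median of 8.61 in positive-change and 4.11 in negative-change peaks (permutation p = 0.0001, the smallest that 10000 permutations can give). Which libraries this value draws on is not given in the sources used here, so it may share reads with the change. In input, the genes of positive-change peaks had a median mean count of 1497 and those of negative-change peaks 3435. The share of positive changes was 28.6% in the least enriched 20% of peaks and 64.8% in the most enriched 20%.

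**Figure D2:**
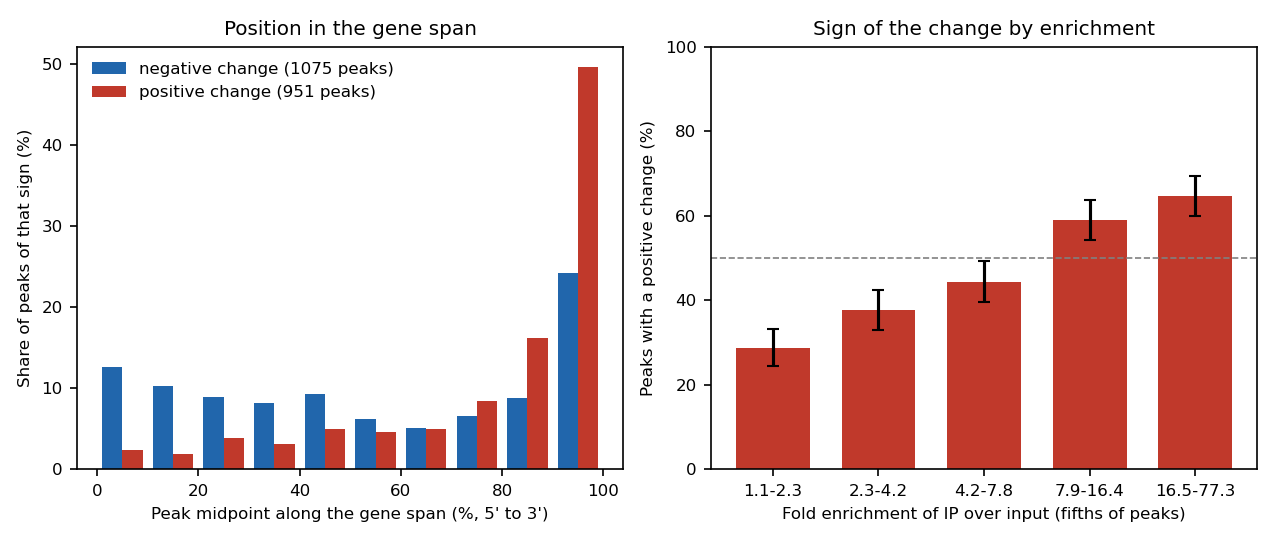
Left, share of peaks of each sign (%) by the peak midpoint along the gene span (%, from 5' to 3'), for 1075 negative-change and 951 positive-change peaks. Right, share of peaks with a positive change (%) in 5 equal classes of fold enrichment with 95% exact intervals, from 28.6% to 64.8%; the dashed line marks equal shares.

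The sign of a peak change, as deposited, was opposite to that of the input change more often than equal to it. Of 973 genes with only negative-change peaks and an adjusted p in input, 382 rose in input and 122 fell, and of 887 genes with only positive-change peaks 127 rose and 217 fell (odds ratio 5.35, Fisher exact p = 4.94e-30). If the peak change is control over knockdown, the same counts give equal directions more often (odds ratio of opposite directions 0.187). Over all tested genes 17.1% rose and 15.5% fell. The median input log2 fold change was 0.12 for genes with negative-change peaks, above all 10000 matched random sets, and -0.06 for genes with positive-change peaks, below all of them. Across 1906 genes, which are not independent replicates, the peak change and the input change had a Spearman rho of -0.27 and a Pearson r of -0.24. Whether the peak change draws on the input libraries is not given in the sources used here. If it does, no relation need not mean a rho of 0 or an odds ratio of 1. The p-values and matched sets here do not account for that. Shared input error alone, simulated for knockdown over control and without the selection of peaks by their change, gave a median rho over peaks of -0.05 (-0.085 to -0.0046), and no such value was computed for a selected list.

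Genes with both changes included Nfic, which rose by 1.39 ± 0.08 in input and carried negative-change peaks of -0.78 and -1.42, and Gse1, which rose by 1.10 ± 0.07 with a peak of -1.22, in the authors' deposited table. Kmt2d, a histone methyltransferase gene, rose by 0.78 ± 0.06 with peaks of -1.08 and -0.56, and Prrc2b by 0.61 ± 0.05 with a peak of -0.71 in the authors' deposited table. Frmd4a and Prrc2a went the same way. Acsl3, which activates fatty acids, fell by 1.08 ± 0.08 in input with a positive-change peak of 0.44 in the authors' deposited table. Eif4ebp1, Tppp3 and H1f0 fell in input and had negative-change peaks, of -2.55 and -0.21 for Eif4ebp1, -1.35 for Tppp3 and -0.31 for H1f0 in the authors' deposited table.

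**Figure D3:**
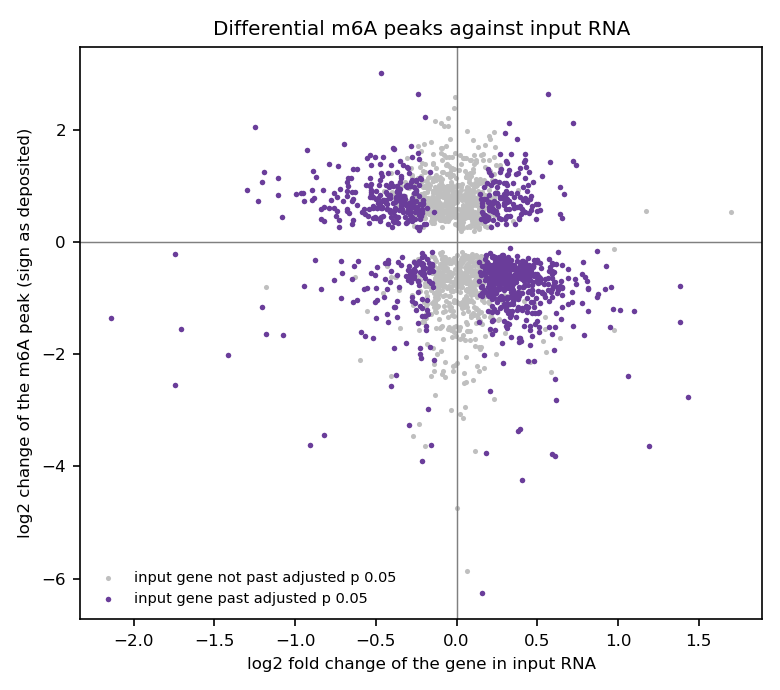
Log2 change of each differential m6A peak, with the sign as deposited, against the log2 fold change of its gene in input RNA, Emg1 knockdown over control, for 2107 peaks. Purple points are genes past an adjusted p of 0.05 in input; the Spearman rho over peaks is -0.28.

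Negative-change peaks were over-represented in 5 gene lists, over a background not matched on expression or on carrying an m6A peak. These lists had median mean counts in input between 2683 and 9265, and the genes of negative-change peaks a median of 3435. More testable peaks on highly expressed genes could raise the shares, which was not tested. Neuronal maturation genes carried them in 13 of 26 members and positive-change peaks in 1, against a negative share of 6.54% over the background (Fisher exact test, adjusted p = 9.65e-08). They included the granin genes Chgb at -0.56 and Chga at -0.65, and the neurofilament gene Nefh at -0.57 in the authors' deposited table. Large subunit assembly factors had negative-change peaks in 13 of 43 members (Fisher exact, adjusted p = 5.97e-05), among them Lyar at -0.61 and Mdn1 at -0.74 in the authors' deposited table, beside the positive-change peak on Mdn1 named above. Translation factors had them in 11 of 39 (adjusted p = 0.000504), including Eif3a at -0.32 and Eef1d at -0.83, and G2/M genes in 8 of 26 (adjusted p = 0.00245), including Mki67 at -0.28 and Cdk1 at -0.60 in the authors' deposited table. Integrated stress response genes had them in 6 of 24 (Fisher exact, adjusted p = 0.0418), among them Atf4 at -0.31 and Cebpb at -2.79 in the authors' deposited table; over genes with a mean of at least 100 that call was lost (adjusted p = 0.13). No list passed for positive-change peaks. Cholesterol synthesis genes carried 4 such peaks (Fisher exact, adjusted p = 0.265), among them those on Srebf2 at 1.11, Lss at 0.83 and Hsd17b7 at 0.98 in the authors' deposited table. Fold enrichments of the peaks named in these lists lay between 1.37 on Atf4 and 21.4 on Eif3a.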

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

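No paired analysis was possible because neither table holds values per library; for the same reason other size factors, no count filter, leaving out each library and an estimated correlation were not run. Alternatives for transcript position and the DRACH motif were not run either. The checks of gene span position were chosen after seeing the data. Counts of changed input genes stayed within 1.5 times under every other threshold, filter and centring tried, except that requiring an absolute log2 fold change of at least 1 left 234 genes, 49 higher and 185 lower, by construction. The same fold limit left 335 negative-change and 249 positive-change peaks. The negative share of peaks ranged from 52.6% with genes counted once to 57.4% with that limit, past the threshold each time. With log2 fold changes in place of Wald statistics, 0 of 28 lists passed, against 18, and the cause was not tested. The 4 alternatives of the list test together ended 24 calls of single lists, and 1 peak list call was lost at a minimum mean of 100. Emg1 and the other named input genes kept their side of the threshold and direction when adjusted over all genes, restricted to means of at least 100 or centred. The position difference stayed past the threshold for the last 20% of the span, at the lower false discovery rate and for peaks of 1 block (odds ratios 3.92, 3.31 and 1.93, against 3.09), smallest for the last of these. Opposite signs of peaks, as deposited, and input had odds ratios from 4.75 to 5.80; with the peak sign turned these are their inverses, 0.187 for the main one. Genes under a mean of 100 were called in 6.46% of cases and the others in 36.5%, so changes of low genes were less detectable.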

Other observations

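Among the tests below, those of the immunoprecipitation explanation and of Rn45s were chosen only after the result was seen, and the grouping by symbol was not planned.

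Genes grouped by the stem of their symbol, in 200 groups of at least 8 tested members, gave 15 groups past an adjusted p of 0.05 (cameraPR), 10 higher and 5 lower. With a preset correlation of 0.05, 4 passed, 2 higher and 2 lower. The 2 lower ones were Rpl and Rps, with 50 and 45 members, which overlap the ribosomal protein lists above. Family names in this paragraph stand for the symbol stem, which can also hold genes outside that family. The Mcm group below shares Mcm2 and Mcm3 with the G1/S list, so these groups are not separate from those calls. The minichromosome maintenance (Mcm) genes, of which 8 of 10 rose and 1 fell, had a median log2 fold change of 0.38 (adjusted p = 3.17e-05). Splicing factor genes with symbols starting in Sf rose in 6 of 10 cases and fell in 0 (adjusted p = 0.000595), and both groups passed with a preset correlation of 0.05 (adjusted p = 0.00126 and 0.0073). Among 13 tetraspanin (Tspan) genes 7 fell and 0 rose (adjusted p = 0.0108), and among 58 Rab GTPase genes 20 fell and 1 rose (adjusted p = 0.0431); at a correlation of 0.05 these had adjusted p of 0.0919 and 0.363. Chromodomain helicase (Chd) genes rose in 6 of 11 cases (adjusted p = 0.0279, and 0.19 at 0.05).

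The target was not the most significant gene: 13 genes had a smaller adjusted p than Emg1, Eif4ebp1 among them, and 7 with a mean of at least 100 fell by at least as much, 2 of them among the 13. Off-target matches of the interfering RNA were not analysed here. Lpcat3, whose span overlaps that of Emg1 by 347 bases on chromosome 6, fell by 0.64 ± 0.09 in the authors' deposited table. Htr3a and Htr3b, the serotonin receptor genes that rose, both lie on chromosome 9 (48899213 to 48911152 and 48935008 to 48964990). These genes were chosen after their values were seen.

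Positive-change peaks lay nearer the 3' end and were more enriched than negative-change peaks. A difference in immunoprecipitation enrichment between conditions may order peaks by strength. Within each of 5 equal classes of enrichment, the share in the last 10% of the span was still higher for positive changes. The difference shrank as enrichment grew, from 43.9 percentage points in the least enriched class to 7.33 in the most enriched. Fisher exact p was under 0.05 in 4 classes and 0.15 in the most enriched. Enrichment class alone did not account for the position difference outside the most enriched class. A single value per peak does not hold an enrichment difference between conditions constant, so that explanation stays open. Position alone did not account for the enrichment difference either: within the last 10% the medians were 6.26 and 4.50, a difference of 1.76 (permutation p = 0.0162). A change in 3' bias of coverage cannot be told apart from the knockdown: the position difference in the shortest 20% of genes was 0.579 of that in the longest 20%, between the bounds set for either reading and with overlapping intervals (4.69 to 21.2 and 12.3 to 31.4 points). From the shortest to the longest of 5 span classes the differences were 12.8, 22.5, 31.8, 24.2 and 22.1 points, so they did not grow steadily with span, which is only a proxy for transcript length. An effect of the knockdown on m6A stays open, untested, and the unstated numerator leaves its direction open.

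Peak changes, with the sign as deposited, went against input changes. Input sampling error shared by both could produce this if the peak change is knockdown over control and draws on the input libraries. The covariance over peaks was -0.0831 (95% bootstrap interval -0.10 to -0.0662), against the -0.0202 that the SEs of the input change give for peaks not selected by their change. The list holds only peaks selected by it, which raises what shared error gives by an unknown amount, so that bound does not hold and shared error stays open in this orientation. If the peak change is control over knockdown, shared error has the other sign and the relation turned to knockdown over control is positive (covariance 0.0831, rho over peaks 0.28). Signal at weakly enriched peaks that does not follow input applies to the first orientation and to a change taken over input. It cannot be told apart from other readings. From the least to the most enriched of 5 classes the slopes were -0.412, -1.05, -0.88, -0.59 and -0.69. The interval of the first (-0.86 to -0.03) left out the -1 this reading gives weak peaks, but the next 2 slopes lay near it, and the last minus the first was -0.28 (-0.74 to 0.20). An m6A-dependent change of RNA level after knockdown is a hypothesis that stays open, untested.

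The entry Rn45s, named for the ribosomal RNA precursor, took 22.0% of the summed mean counts of this poly(A) data. Rn45s fell by 0.54 ± 0.06 in the authors' deposited table, and Lars2, with 1.10% of the counts, fell by 0.66 ± 0.19. The log2 fold change of Rn45s divided by its SE was -9.64, which restates the choice of the gene and tests nothing. Lower carry-over of RNA without a poly(A) tail may lower Rn45s and stays open: the replication-dependent histone list had a median of 0.314 (95% bootstrap interval 0.02 to 0.60; without H1f0 0.35, 0.02 to 0.69), above the change of Rn45s, but its members went both ways. Hist2h2bb at -0.47 ± 0.10 and Hist1h1b at -0.50 ± 0.13 in the authors' deposited table fell about as Rn45s did, while 4 others with a mean of at least 100, Hist1h4d at 0.69 ± 0.20 among them, had intervals above 0. A count per gene cannot tell reads of the precursor from reads of mature ribosomal RNA, so the level of the precursor itself was not measured. A lower level of the precursor after Emg1 knockdown is a hypothesis, found on these data and untested. Reads shared among copies of the precursor were not examined.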
